A study of Mus musculus with 23 samples.

How the data were processed

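RNA of 23 libraries was analysed, from 8 wild-type, 8 GRK-haploinsufficient and 7 GRK triple-knockout mouse hearts at embryonic day 13.5. Per the labels' protocols, hearts were flash frozen, RNA was extracted with Trizol, ribosomal RNA was depleted, the RNA was fragmented chemically and libraries were sequenced from a single end without keeping the strand. Overlapping and antisense transcripts can therefore not be told apart. All 3 groups carry the same strain label. Groups were taken from the genotype labels.

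The deposited count table of the authors holds integer read counts for 23512 features: 23453 genes, 58 single exons or untranslated parts of the targeted genes and the Cre transgene. Per the submitters' processing notes, reads were aligned to mm10 with TopHat2 (version 2.0.10) and Bowtie2 and counted with HTSeq. The deposited FPKM values of the authors, 23885 entries with 23405 names, were made with Cufflinks (version 2.1) per the same notes. Versions of the other tools are not given there. Classes of unassigned reads are not part of the count table and were not used here. Reads were not realigned.

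Counts were tested with edgeR (version 4.0.16) in R (version 4.3.3), in a quasi-likelihood fit over all 23 libraries with a coefficient per group and a term for the library ID set (IDs 1 to 12 or 19 to 30), which holds 4 and 4 wild-type, 4 and 4 haploinsufficient, and 3 and 4 triple-knockout libraries. Library sizes were scaled by TMM. Genes were kept by the edgeR expression filter with a minimum count of 10 and a minimum total of 15, which left 13941 apart from the targeted genes, their single exons and Cre, which are in none of the counts of called genes, and the common biological coefficient of variation was 0.208. P-values were two-sided and adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05. CPM values use the TMM-scaled library sizes, and log2 CPM uses a prior count of 1. A gene was called where its adjusted p was under the threshold, and rose, fell and changed are used for called genes and lists only. The single features were adjusted among the 24 tested. Levels of the exon groups were compared by exact permutation of libraries between groups on log2(CPM + 1), and pooled ratios carry exact 95% counting intervals.

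The 34 gene lists were tested with camera (limma version 3.58.1) at its preset correlation of 0.01, again with camera and an estimated correlation, and with fry. Members were counted as called over all genes and as adjusted over the list alone. Sharing of calls between the GRK groups was compared with 20 simulated draws of unchanged groups and with 20 splits of the wild-type libraries between the comparisons. Positions of called genes were compared with windows of 10 Mb around the targeted loci, and of 5 and 20 Mb, by Fisher's exact test.

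The groups, comparisons, main test, lists and most alternatives were fixed before the data were examined. The alternatives were DESeq2 (version 1.42.0), limma on log2 FPKM, other scaling, no filter, no ID set term, a sex term, the replicate number as a block, each ID set alone, only the groups compared, and each library left out. Alternatives chosen after seeing the data left out libraries with a high score of lung, foregut, liver and thymus markers, used that score as a term, corrected offsets for exon length, or used exon groups. The text names the targeted genes and features. In each comparison it names the 10 highest and the 10 lowest log2 fold changes among called genes with a mean of at least 1 log2 CPM, leaving out Xist, Tsix, Y-linked genes, single-exon features, Cre and unnamed gene models. It names up to 4 members with the smallest p per list described, and up to 4 called genes with the smallest p near each targeted locus. Some items this rule picks are not reported here. Other genes named are said to have been chosen after their values were seen.

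The fit was tested on simulated data with 50 genes at each of 4 fold changes. For the triple knockout against wild type it recovered 62% of genes shifted 1.5-fold, 84% of those shifted 2-fold and 96% of those shifted 3-fold, with 7 false calls among 177. For the haploinsufficient group these shares were 46%, 84% and 86% with 6 false calls among 163, and between the GRK groups 68%, 74% and 92% with 5 false calls among 169. No pair of libraries of a group agreed as closely as a resequenced library would: the lowest chi-square per degree of freedom was 5.38, between haploinsufficient replicates 1 and 2.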

Results

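RNA was sequenced from hearts of mouse embryos at embryonic day 13.5 in 3 genotype groups. The 8 wild-type hearts carried no Cre and unmodified Grk2, Grk5 and Grk6. The 8 GRK-haploinsufficient hearts carried a floxed Grk2 allele beside a wild-type allele, floxed Grk5 on both alleles, Grk6 knocked out on both alleles and the Nkx2.5Cre driver, which expresses the Cre recombinase in the cardiac lineage. The 7 triple-knockout hearts differed from these by label in a single respect, floxed Grk2 on both alleles. The 3 kinases phosphorylate activated G-protein coupled receptors, after which arrestins bind the receptor and dampen its signal. The series concerns defects of the atrioventricular canal, from which the valves and part of the septum form, in hearts without these kinases. The total count per library ran from 3838166 to 14050559 in the wild-type group (median 6657773.5), from 1757257 to 11025358 in the haploinsufficient group (median 4489026.5) and from 6657734 to 13864731 in the triple-knockout group (median 7270188). At the limit of 3 counts, a gene with no count in a library could be present there at up to 0.214 CPM (counts scaled by library size) in the deepest library and up to 1.71 CPM in the shallowest. Intervals and limits of this kind cover counting error only. The labels do not say that each replicate was a separate embryo, so the p-values measure the spread between these samples, which may be technical in part. Xist outweighed Y-linked genes in 5 wild-type, 5 haploinsufficient and 3 triple-knockout libraries, and the reverse held in 3, 3 and 4. Both sexes in each group argue against a single embryo behind a group. They do not show that every library came from a separate embryo.

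The Cre transgene and the targeted genes were examined before any other gene. Cre stood at 17.7 ± 4.90 CPM (SD, n = 8) in the haploinsufficient libraries, between 9.89 and 23.9, and at 18.5 ± 5.61 CPM (SD, n = 7) in the triple-knockout libraries, between 8.21 and 24.9. In the wild-type libraries 20 counts spread over 6 of the 8 libraries gave 0.332 ± 0.341 CPM (SD, n = 8). Grk2 is listed under its older symbol Adrbk1 (mm10, chromosome 19, 4286001 to 4305955). Whole-gene levels of the 4 targeted genes are sums of the counts on their single-exon and untranslated features. Such a sum can be partial: Grk5 exon 10 and Grk6 exons 10, 18 and 19 held 0 counts in every group. For Adrbk1 the whole-gene level was 54.3 ± 4.25 CPM in wild-type hearts (SD, n = 8), 42.5 ± 12.05 in haploinsufficient hearts (SD, n = 8) and 34.4 ± 6.60 in triple-knockout hearts (SD, n = 7). It fell in the triple knockout (log2 fold change -0.65 ± 0.14 SE, edgeR adjusted p = 0.0121) and did not pass the test in the haploinsufficient group (-0.33 ± 0.14, edgeR adjusted p = 0.207). Grk5 (chromosome 19, 60889749 to 61092555) went from 23.9 ± 2.50 CPM to 13.4 ± 2.24 in the haploinsufficient group and 14.2 ± 3.35 in the triple knockout. It fell in both, with log2 fold changes of -0.85 (edgeR adjusted p = 0.000635) and -0.76 (edgeR adjusted p = 0.00220). Grk6 (chromosome 13, 55445334 to 55460927) went from 30.7 ± 3.22 CPM to 15.7 ± 4.38 and 14.96 ± 3.42, with log2 fold changes of -0.94 (edgeR adjusted p = 0.000563) and -1.04 (edgeR adjusted p = 0.000158). Nkx2-5 (chromosome 17, 26838665 to 26841565), the cardiac transcription factor gene after which the driver is named, went from 98.3 ± 10.4 CPM to 70.2 ± 16.2 and 49.7 ± 12.9. Nkx2-5 fell in the triple knockout (-0.98, edgeR adjusted p = 0.000294), whereas -0.50 in the haploinsufficient group missed the threshold (edgeR adjusted p = 0.0667). Between the triple knockout and the haploinsufficient group none of the 4 genes passed the edgeR test: -0.32 for Adrbk1, 0.09 for Grk5, -0.10 for Grk6 and -0.48 for Nkx2-5 (edgeR adjusted p = 0.279, 0.818, 0.802 and 0.141). The deposited FPKM values of the authors were added up over entries under the gene's symbol or its exon names. A sum of this kind need not equal an FPKM of the whole gene, so only the order of the groups is read from it. For Adrbk1 these sums ran the same way, at 24.6 ± 1.78, 18.99 ± 4.50 and 15.6 ± 3.54 in the wild-type, haploinsufficient and triple-knockout groups.

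Counts were also read on groups of single exons, which were chosen after the values had been seen. A near-complete loss over the group was seen for Grk6 only. Grk6 exons 3 to 9 held 852 counts in the wild-type group (14.5 ± 2.58 CPM), 12 in the haploinsufficient group (0.343 ± 0.314 CPM) and 4 in the triple knockout (0.0641 ± 0.0891 CPM). The pooled ratio was 0.0213 of wild type for the haploinsufficient group (95% exact counting interval 0.0110 to 0.0374) and 0.00439 for the triple knockout (0.00119 to 0.0113). Both differences gave a two-sided exact permutation p of 0.000155, the smallest that 8 against 8 or 8 against 7 libraries can give. Grk5 exons 7 to 8 stood at 0.223 of wild type in the haploinsufficient group (0.137 to 0.347) and at 0.342 in the triple knockout (0.248 to 0.466), with exact permutation p = 0.00124 for each. Grk5 exons outside this group varied in the haploinsufficient group, with exon 11 at 0.271 against 1.13 CPM in wild-type hearts, exon 15 at 1.16 against 1.14 and exon 3 at 0.598 against 0.327. Adrbk1 exons 3 to 6 stood at 0.625 of wild type in the haploinsufficient group (0.457 to 0.846, exact permutation p = 0.0193) and at 0.549 in the triple knockout (0.417 to 0.719, exact permutation p = 0.0126), an interval that holds the whole-gene ratio of 0.669. The triple knockout held 0.878 of the haploinsufficient level over these Adrbk1 exons (0.628 to 1.24, exact permutation p = 0.874). A loss of Grk2 beyond that of the haploinsufficient hearts was therefore not detectable in the exons at this depth, with 88 and 62 counts. Nkx2-5 was read exon by exon, without a test of the difference between exons. Exon 2 fell in the haploinsufficient group from 64.8 ± 7.90 to 38.3 ± 9.87 CPM (-0.78, edgeR adjusted p = 0.000106 over the 24 features tested). Nkx2-5 exon 1 was at 33.5 ± 2.77 and 31.95 ± 8.28 CPM there (-0.09, edgeR adjusted p = 0.742). In the triple knockout both exons fell, exon 1 by 0.63 (edgeR adjusted p = 0.00259) and exon 2 by 1.20 (edgeR adjusted p = 1.34e-07).

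**Figure D1:**
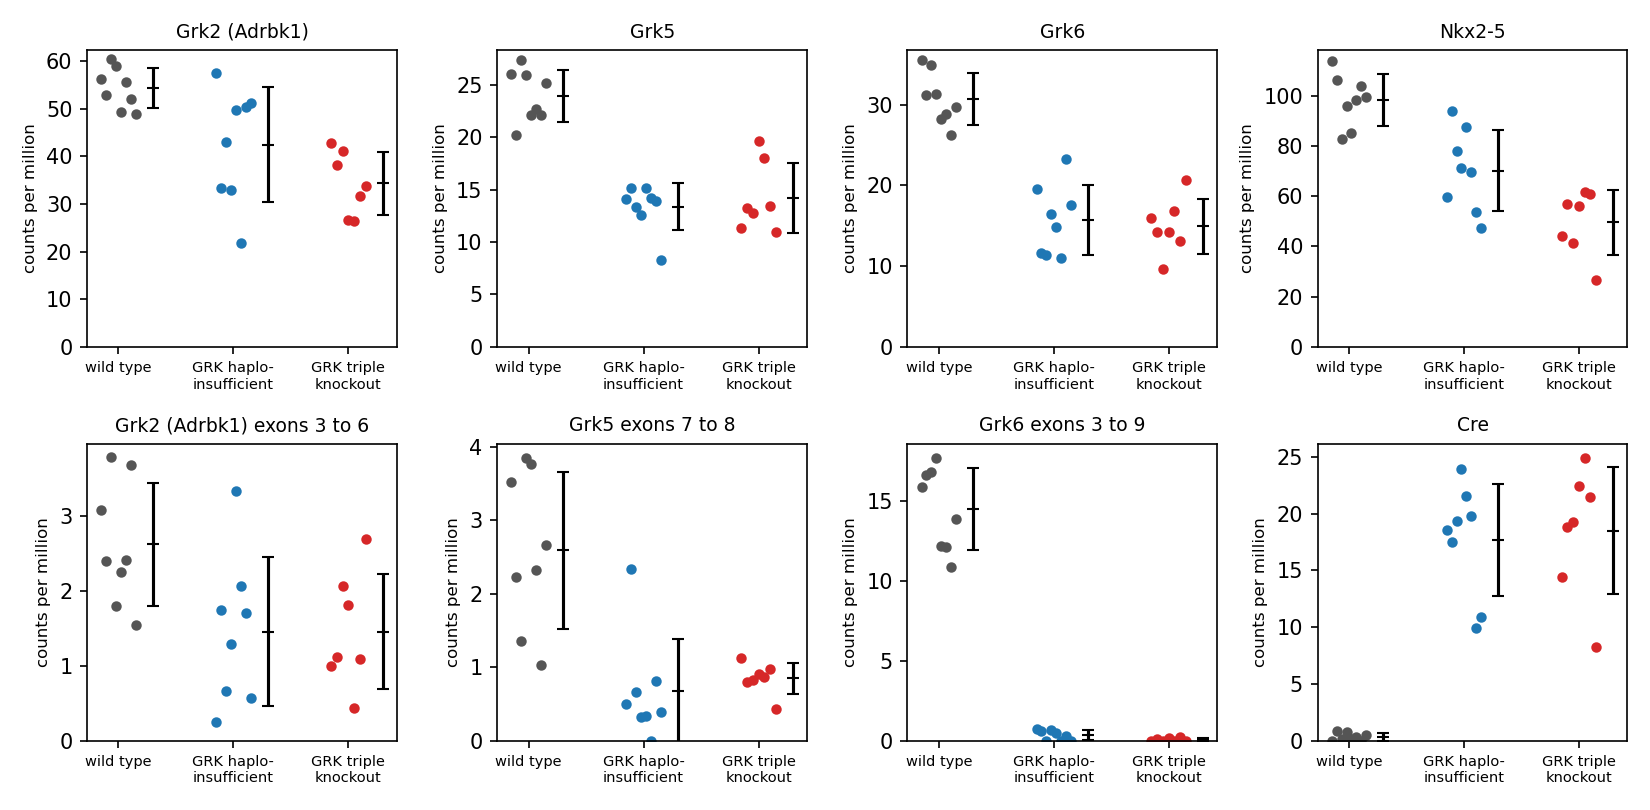
CPM of the 4 targeted genes, 3 exon groups and Cre in each library (points) of the wild-type, GRK-haploinsufficient and GRK triple-knockout groups, with the mean and SD of each group as bars. Cre separates the wild-type libraries from all others, and counts on Grk6 exons 3 to 9 reach 0.742 CPM at most in the haploinsufficient group against at least 10.85 CPM in the wild type.

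Triple-knockout hearts were compared with wild-type hearts to ask what differs in the transcriptome where both alleles of all 3 kinase genes are targeted. Tnnt3, the troponin T of fast skeletal muscle, rose 8.72-fold from 6.66 ± 2.07 to 58.3 ± 26.7 CPM (SD, n = 8 and 7, edgeR adjusted p = 6.46e-09). Acan, the large proteoglycan of cartilage, was 3.03-fold lower at 4.85 ± 1.74 against 14.3 ± 3.35 CPM (edgeR adjusted p = 0.000139). Genes of cholesterol synthesis rose as a group, led by Hmgcs1 at 0.68 ± 0.09 log2 (SE). The potassium channel subunit gene Kcne1, a gene of ventricular muscle, fell by 0.81 ± 0.16. In all, 166 of 13941 genes passed the edgeR test, the targeted genes and Cre not counted, 68 higher and 98 lower, and 139 of them changed by at least 0.5 on the log2 scale.

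Among the other genes with the largest increases, the fast myosin heavy chain gene Myh2 was 17.5-fold higher (3.18 ± 1.99 against 0.169 ± 0.234 CPM). Aldh1a7, an aldehyde dehydrogenase gene, rose by 3.00 on the log2 scale, the neural adhesion molecule gene L1cam by 2.14, the glutamate receptor gene Grin2c by 1.89 and Stab2, a scavenger receptor of sinusoidal endothelium, by 1.74. Dynlt1b, a dynein light chain gene with near-identical copies, gave 1.90 and is uncertain for that reason. Rprl3, Rprl2 and Rprl1 gave 6.09, 5.54 and 4.75, while Rpph1, the RNA of ribonuclease P, fell by 1.58 from 16790 ± 2368 to 5590 ± 822 CPM. The Rprl genes are near-identical relatives of Rpph1, so reads could be divided between them and these 4 values are uncertain. Large decreases were those of the netrin receptor gene Unc5a (-2.02), Lyz1 (-1.87), the cytokine receptor gene Crlf2 (-1.77), the cartilage matrix genes Comp (-1.73) and Acan (-1.60), Tmem88b (-1.69), the lectin gene Clec4g (-1.66) and Lrtm1 (-1.52). Lyz1 shares reads with its copy Lyz2 and is uncertain too. The edgeR adjusted p of these genes ran from 4.18e-11 for Rprl2 to 0.0440 for Aldh1a7.

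Of 34 gene lists, 8 were called against wild type with camera at its preset correlation, 2 higher and 6 lower. Cholesterol synthesis held 7 of 24 members that rose over all genes tested and 14 adjusted over the list alone (camera adjusted p = 1.05e-18, and adjusted p = 0.000819 with an estimated correlation). Besides Hmgcs1 these included Insig1 (0.66 ± 0.12) and the cholesterol carrier gene Stard4 (0.55 ± 0.13). The list of GPCR kinases and arrestins, had 3 of 8 members lower, and 4 adjusted over the list alone. The 3 are the engineered genes themselves, so the call follows from the design. Its camera adjusted p was 0.000218, and adjusted p = 0.00497 with an estimated correlation, with Grk4 at -0.70 ± 0.29 (edgeR adjusted p = 0.341). Of 15 ventricular genes, 3 fell over all genes and 3 adjusted over the list alone: Nkx2-5, Kcne1 (edgeR adjusted p = 0.00562) and the guidance ligand gene Slit2 (-0.64 ± 0.14). Camera gave an adjusted p of 0.000342 for this list, and adjusted p = 0.598 with an estimated correlation, and with a score of lung and foregut markers in the model it turned direction (camera adjusted p = 0.9892). Nkx2-5 is itself a targeted locus. Of 26 cardiac transcription factors, Nkx2-5 fell over all genes and 4 fell adjusted over the list alone, with Irx3 at -0.72 ± 0.20 and Myocd at -0.41 ± 0.13 (camera adjusted p = 0.0141, and adjusted p = 0.598 with an estimated correlation). Of 28 sarcomere genes, Csrp3, a Z-disc protein gene, fell over all genes (-0.47 ± 0.12) and 3 fell adjusted over the list alone (camera adjusted p = 0.0141, and adjusted p = 0.770 with an estimated correlation). This list turned direction with the lung and foregut marker score in the model (camera adjusted p = 0.227) and without the libraries in which that score was high (0.288). Of 20 immediate early genes, the matricellular gene Ctgf fell over all genes (-0.64 ± 0.14) and 4 fell adjusted over the list alone (camera adjusted p = 0.000612, and adjusted p = 0.138 with an estimated correlation). The oxidative phosphorylation list was called lower (camera adjusted p = 0.000590, and adjusted p = 0.770 with an estimated correlation) with 0 of 28 members called by edgeR over all genes or adjusted over the list alone. For it 3 members had an unadjusted p under 0.05, DESeq2 and limma called 0 as well, and without the libraries of a high score the list turned direction (camera adjusted p = 0.373).

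Markers of neural crest, neurons and Schwann cells were called higher (camera adjusted p = 6.71e-05, and adjusted p = 0.254 with an estimated correlation). Of its 13 measured members Gap43, a growth cone protein gene, rose over all genes (0.55 ± 0.11, edgeR adjusted p = 0.00389) and 7 rose adjusted over the list alone. Dbh, the enzyme that makes noradrenaline, was at 2.07 ± 0.62 and the neuronal filament gene Prph at 1.61 ± 0.55, neither past the threshold over all genes. The 35 measured genes of the atrioventricular canal and cushions were not called (camera adjusted p = 0.339). Of these, the cartilage collagen gene Col2a1 alone fell, over all genes and adjusted over the list alone (-1.11 ± 0.27, edgeR adjusted p = 0.0299). Bmp5 was at 0.44 ± 0.17 and Bmp4 at 0.23 ± 0.10, with edgeR adjusted p = 0.289 and 0.349. In the list of skeletal muscle and cartilage markers Tnnt3 and Tnni2 (0.82 ± 0.17) rose and Acan and Col2a1 fell, the same 2 and 2 adjusted over the list alone. Its median was -0.12 while its mean of 0.10 and its test pointed up (camera adjusted p = 0.856). Of 24 endothelial and endocardial markers, the natriuretic peptide receptor gene Npr3 fell (-0.46 ± 0.10) and Lyve1 rose (0.98 ± 0.24), and 1 rose and 3 fell adjusted over the list alone (camera adjusted p = 0.339).

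The markers of lung, foregut, liver and thymus, tissues that lie beside the heart, were not evenly spread over the groups. The mean log2 score of this list against the wild-type mean was 0.955 ± 0.838 (SD, n = 7) in the triple knockout, and replicates 1, 3 and 7 stood at 1.95, 1.74 and 1.57. No wild-type library was above 1.40. The list itself was not called in the triple knockout (camera adjusted p = 0.0726, and adjusted p = 0.378 with an estimated correlation), with 0 of 13 members called by edgeR over all genes, 3 higher adjusted over the list alone, 5 at an unadjusted p under 0.05, and 0 by DESeq2 and by limma. Without the libraries that scored above 1.5 in any group, a choice made after seeing the data, 83 genes passed the edgeR test, 72 of them among the 166, and with the score as a term 189 passed, 110 of them among the 166. DESeq2 called 279 genes, and edgeR on only these groups called 296, on library IDs 1 to 12 alone 50 and on IDs 19 to 30 alone 51.

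**Figure D2:**
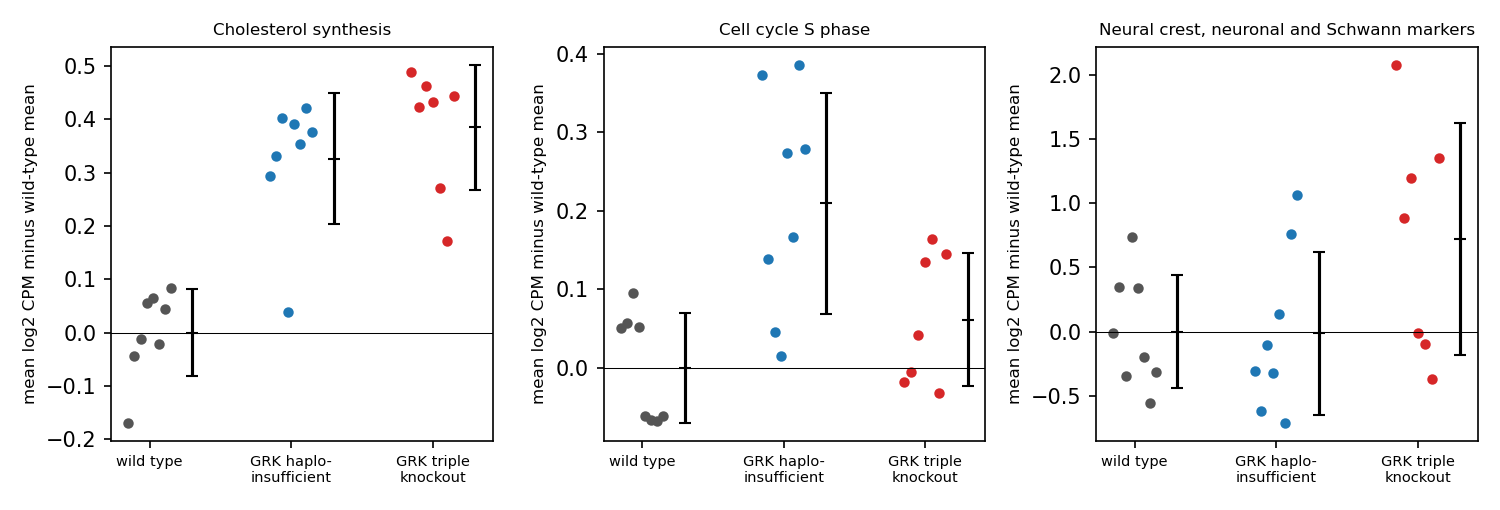
Mean log2 CPM of the members of 3 gene lists in each library (points), relative to the wild-type mean, with the mean and SD of each group as bars. All cholesterol synthesis scores of both GRK groups except that of haploinsufficient replicate 4, at 0.0386, lie above the wild-type libraries.

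Haploinsufficient hearts were compared with wild-type hearts to see what a remaining wild-type Grk2 allele leaves changed. Ryr3, a calcium release channel gene, was 3.00-fold lower (29.3 ± 9.53 against 88.8 ± 20.6 CPM, SD, n = 8 each, edgeR adjusted p = 5.00e-07). Tnnt3 rose 5.01-fold to 34.04 ± 12.6 CPM (edgeR adjusted p = 1.77e-06). Genes of cholesterol synthesis rose as a group, and Cdh5, the cadherin of endothelial junctions, fell (-0.60 ± 0.11). In all, 312 of 13941 genes passed the edgeR test, 120 higher and 192 lower, and 220 of them changed by at least 0.5 on the log2 scale.

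Several of the largest increases were in genes with a wide spread between libraries. Foxf1, a transcription factor of foregut and lung mesenchyme, was at 18.9 ± 24.5 against 1.47 ± 2.63 CPM (4.12 on the log2 scale, edgeR adjusted p = 0.0342). Its neighbouring long noncoding RNA gene Fendrr was at 3.59 ± 3.96 against 0.223 ± 0.402 CPM (4.42, edgeR adjusted p = 0.0284) and the epithelial tight junction gene Cldn6 at 14.2 ± 16.9 against 1.19 ± 2.86 CPM (4.22, edgeR adjusted p = 0.0424). Adh1, an alcohol dehydrogenase gene, rose by 3.51 and Aldh1a7 by 3.12, while Myh2 rose by 3.94 to 2.71 ± 1.64 CPM. The uncertain Rprl3, Rprl2 and Rprl1 gave 6.51, 6.43 and 5.48. Large decreases were those of Unc5a (-2.21), the glycosyltransferase gene B3gnt3 (-2.19), the uncertain Lyz1 (-1.98), Lrtm1 (-1.66), the anion transporter gene Slc26a1 (-1.62), the diacylglycerol kinase gene Dgkk (-1.59), Tmem180 (-1.59) and Acan (-1.58). The highest edgeR adjusted p in this set was 0.0424, for Cldn6.

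Camera called 9 of the 34 lists, 5 higher and 4 lower. With offsets corrected for exon length, 8 kept the call and 1 lost it. All 24 cholesterol synthesis genes had a positive fold change, 9 rose over all genes and 12 adjusted over the list alone (camera adjusted p = 1.64e-13, and adjusted p = 0.00461 with an estimated correlation). Examples were Hmgcs1 (0.51 ± 0.09), Insig1 (0.67 ± 0.12) and Cyp51 (0.52 ± 0.11). Of 24 S phase genes, 23 had a positive fold change, Uhrf1, which maintains DNA methylation at replication, rose over all genes (0.33 ± 0.09) and 10 rose adjusted over the list alone (camera adjusted p = 2.01e-07, and adjusted p = 0.158 with an estimated correlation). The replication helicase gene Mcm4 was at 0.40 ± 0.11 and the helicase partner gene Gins2 at 0.41 ± 0.12, with edgeR adjusted p = 0.0508 and 0.0696. The highest S phase scores were those of replicates 7, 1 and 8 (0.386, 0.373 and 0.279), the libraries that also scored highest for lung and foregut markers, and the list was still called by camera without these libraries and with the marker score as a term. The list of mitosis genes was called higher with a median of 0.12 (camera adjusted p = 0.00658, and adjusted p = 0.474 with an estimated correlation), and that of ribosomal proteins with a median of 0.19 (camera adjusted p = 8.46e-06, and adjusted p = 0.613 with an estimated correlation). In both, edgeR called 0 members over all genes and 0 adjusted over the list alone, 8 members had an unadjusted p under 0.05, and DESeq2 and limma called 0. The kinases and arrestins, a list that holds the engineered genes and is called by design, were lower (Grk5 and Grk6, 2 of 8 over all genes, 4 adjusted over the list alone, camera adjusted p = 0.000375, and adjusted p = 0.00776 with an estimated correlation).

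Of 24 endothelial and endocardial markers, 4 fell over all genes, and 5 fell and 1 rose adjusted over the list alone (camera adjusted p = 0.0189, and adjusted p = 0.338 with an estimated correlation). These were Cdh5 (edgeR adjusted p = 0.00376), Npr3 (-0.51 ± 0.10), the angiopoietin receptor gene Tek (-0.45 ± 0.09) and Ramp2 (-0.38 ± 0.10). Of 22 genes of Notch signalling and trabeculation, Bmp10, a ligand made by trabecular myocardium, fell over all genes (-0.71 ± 0.17, edgeR adjusted p = 0.0255) and 4 fell adjusted over the list alone (camera adjusted p = 0.00126, and adjusted p = 0.194 with an estimated correlation). Of 22 conduction and ion channel genes, the potassium channel gene Kcnd2 fell over all genes (-1.10 ± 0.24, edgeR adjusted p = 0.00996) and 4 fell adjusted over the list alone (camera adjusted p = 0.0246, and adjusted p = 0.194 with an estimated correlation). In the atrioventricular canal and cushion list Bmp5, a growth factor gene of the canal myocardium, rose over all genes (0.70 ± 0.17, edgeR adjusted p = 0.0273), and 2 rose and 2 fell adjusted over the list alone. Its median of -0.07 and its test pointed down and its mean of 0.03 up (camera adjusted p = 0.487). Of 24 extracellular matrix genes, the fibronectin gene Fn1 (-0.62 ± 0.15) and the proteoglycan gene Bgn (-0.36 ± 0.10) fell over all genes, and 1 rose and 4 fell adjusted over the list alone (camera adjusted p = 0.0606).

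The lung, foregut, liver and thymus list was called higher in haploinsufficient hearts (camera adjusted p = 0.00209, and adjusted p = 0.0923 with an estimated correlation). Of its 13 members 7 rose adjusted over the list alone and 0 over all genes, where 7 had an unadjusted p under 0.05, DESeq2 called 1 and limma 0. The epithelial genes Epcam and Foxa2 were at 3.82 ± 1.08 and 4.19 ± 1.26, with edgeR adjusted p = 0.0579 and 0.0767. The score of this list averaged 1.07 ± 1.16 (SD, n = 8), with replicates 1, 7 and 8 at 2.101, 2.41 and 2.35. Of 20 Hedgehog targets Foxf1 rose and the co-receptor gene Cdon fell (-0.38 ± 0.09, edgeR adjusted p = 0.0283), with the same members called adjusted over the list alone (camera adjusted p = 0.542). The pathway target Gli1 was at 2.49 ± 0.90 with an edgeR adjusted p of 0.147. The list does not separate targets that signalling raises from those it lowers, so its direction is not a direction of signalling. Without the libraries above a score of 1.5, a choice made after seeing the data, 109 genes passed, 81 of them among the 312, and with the score as a term 155 passed, 101 of them among the 312. DESeq2 called 528 genes, library IDs 1 to 12 alone gave 20 and IDs 19 to 30 alone 179, and leaving out single libraries gave 153 (without wild-type replicate 8) to 615 (without haploinsufficient replicate 3).

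**Figure D3:**
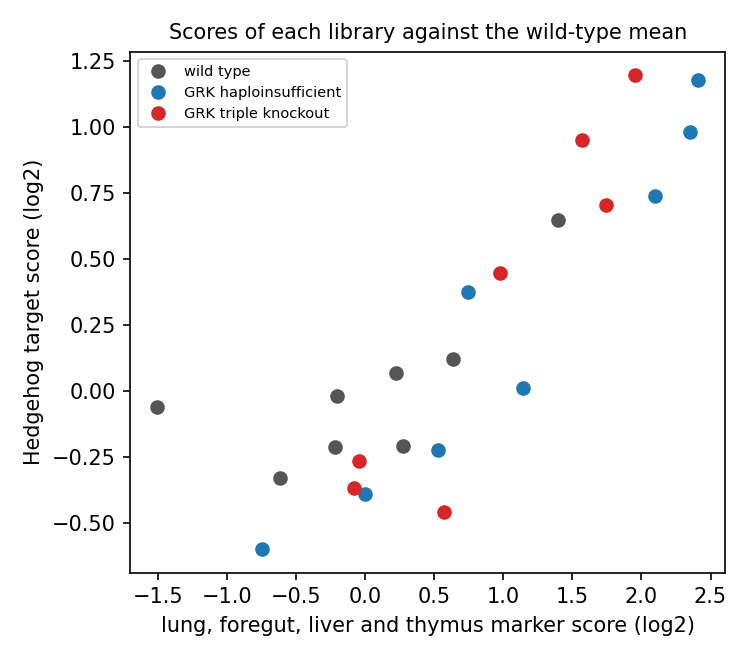
Score of the Hedgehog targets (vertical axis) against the score of lung, foregut, liver and thymus markers (horizontal axis) in each library, both as mean log2 CPM relative to the wild-type mean, coloured by group. The libraries with the highest marker scores, up to 2.41 in haploinsufficient replicate 7, also have high Hedgehog target scores, and those of a low marker score lie in all 3 groups.

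Triple-knockout hearts were then compared with haploinsufficient hearts, a contrast in which only Grk2 differs by label. The replication-dependent histone gene Hist1h2af was lower in the triple knockout (2.36-fold, 11.8 ± 4.13 against 27.9 ± 10.1 CPM, SD, n = 7 and 8, edgeR adjusted p = 0.00575). Cdon, a co-receptor of Hedgehog ligands, was higher at 132.7 ± 16.7 against 92.1 ± 16.1 CPM (0.53 ± 0.10 on the log2 scale, edgeR adjusted p = 0.0164), and the laminin gene Lama2 was at 123.7 ± 16.5 against 90.7 ± 14.02 CPM (0.45 ± 0.10). Rplp2, a protein of the ribosomal stalk, was lower at -0.65 ± 0.12 (edgeR adjusted p = 0.0164). In all, 55 of 13941 genes passed the edgeR test, 11 higher and 44 lower.

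The further genes higher in the triple knockout were the calcium channel gene Cacna1b (1.76), the aminopeptidase gene Anpep (1.19), the collagen gene Col6a6 (0.89), the signalling adaptor gene Frs2 (0.79), Tmem255a (0.67), Slc35b4 (0.61), the Mediator subunit gene Med13 (0.44) and Ppp1r9a (0.43). Those lower were the histone genes Hist1h2an (-1.02), Hist1h3c (-1.01), Hist1h4k (-0.98), Hist1h2ae (-0.92) and Hist1h2ak (-0.91), Scand1 (-1.21), the small nucleolar RNA gene Snora78 (-0.96), the respiratory complex gene Ndufc1 (-0.91) and the cytochrome oxidase assembly gene Coa6 (-0.88). Their highest edgeR adjusted p was 0.0477. Histone gene copies share sequence, so the value of each single copy is uncertain. Of the 55 genes whose symbols begin with Hist and a digit, a set chosen after its values were seen, 17 were lower and the median log2 fold change was -0.67, against 0 called and a median of -0.33 with offsets corrected for exon length. Their exon length had a median of 468 nt against 2940 nt over all genes tested. Across genes, which are not independent replicates, the log2 fold change rose with exon length (Spearman's rho 0.449), while it rose by less against wild type in the triple knockout (0.223) and fell in the haploinsufficient group (-0.255).

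Camera called 6 lists in this contrast, 3 lower and 3 higher, and with an estimated correlation 0 were called, as with fry. With offsets corrected for exon length, 4 of the 6 lost the call, those of ribosomal proteins, oxidative phosphorylation, extracellular matrix and Notch and trabeculation. Of 30 ribosomal protein genes none had a positive fold change, Rplp2 was lower over all genes and 8 were lower adjusted over the list alone (camera adjusted p = 1.21e-11, and adjusted p = 0.696 with an estimated correlation). Oxidative phosphorylation was lower with a median of -0.21 (camera adjusted p = 2.38e-06, and adjusted p = 0.721 with an estimated correlation), and S phase genes with a median of -0.13 (camera adjusted p = 0.000275, and adjusted p = 0.696 with an estimated correlation). In both, edgeR called 0 members over all genes and 0 adjusted over the list alone, with 9 and 8 members lower at an unadjusted p under 0.05, and DESeq2 and limma called 0. Extracellular matrix genes were higher with a median of 0.22 (camera adjusted p = 0.00719, and adjusted p = 0.696 with an estimated correlation). Among these the matrix proteoglycan gene Bgn was at 0.35 ± 0.10, and edgeR called 0 over all genes and 1 adjusted over the list alone, with 3 higher and 1 lower at an unadjusted p under 0.05, 1 by DESeq2 and 0 by limma. The Notch and trabeculation list was higher (camera adjusted p = 0.0108, and adjusted p = 0.696 with an estimated correlation) with 3 higher and 1 lower adjusted over the list alone and 0 over all genes. In it 8 were higher and 1 lower at an unadjusted p under 0.05, DESeq2 called 1 lower and limma 0, the ligand gene Jag1 was at 0.45 ± 0.13 and Irx3 at -0.80 ± 0.20. The neural crest, neuronal and Schwann list was higher with a median of 0.59 (camera adjusted p = 0.0156, and adjusted p = 0.696 with an estimated correlation), with 0 called by edgeR over all genes and adjusted over the list alone, 2 at an unadjusted p under 0.05, and 0 by DESeq2 and limma. The atrioventricular canal and cushion list had 0 members called over all genes and 0 adjusted over the list alone (camera adjusted p = 0.905), with 2 higher and 2 lower at an unadjusted p under 0.05 and 0 called by DESeq2 and limma.

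The count of 55 depended on the method and on the libraries used. Limma on log2(FPKM + 1) called 0 genes (2486 at an unadjusted p under 0.05), edgeR with offsets corrected for exon length called 0 (1371 at an unadjusted p under 0.05) and edgeR without the libraries of a high lung and foregut score called 0 (803 at an unadjusted p under 0.05), against 251 by DESeq2 and 2136 at an unadjusted p under 0.05 in the reported edgeR fit. Leaving out single libraries gave 10 (without triple-knockout replicate 3) to 417 (without haploinsufficient replicate 3).

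**Figure D4:**
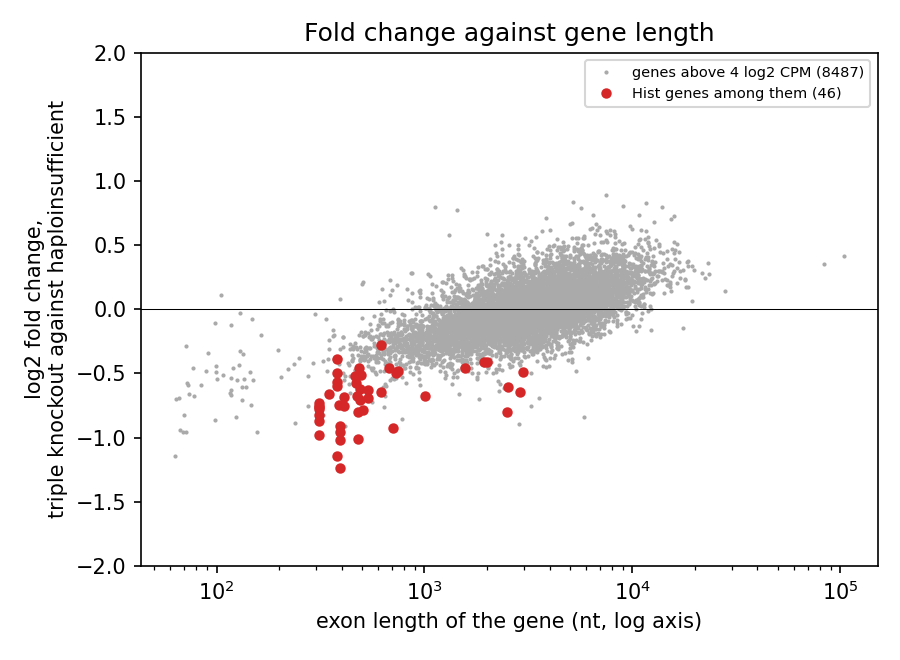
Log2 fold change, triple knockout against haploinsufficient, of each gene above 4 log2 CPM (grey) against its exon length on a log axis in nt, with the Hist genes in red. Shorter genes lie lower across the range, and the Hist genes lie lower than most genes of the same length.

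Both GRK groups were set beside each other to see how far their differences from wild type coincide. Of the 166 genes called in the triple knockout and the 312 called in the haploinsufficient group, 98 were called in both with the same direction, 43 higher and 55 lower, and 0 with opposite directions. Tnnt3, Myh2, Hmgcs1, Unc5a and Acan are among these. Independent lists of these sizes would share 0.585 higher and 1.35 lower. In 20 simulations of unchanged groups against the same controls, 0.05 and 0.1 genes were called on average, so those draws give no measure of how many calls would be shared. The log2 fold changes had a correlation of 0.643 across genes, against 0.478 in these simulations, and a covariance of 0.0783 against 0.0236, a difference of 0.0547. With the 8 wild-type libraries split 4 and 4 between the comparisons, 20 splits gave between 27 and 35 shared genes (mean 30.6) among means of 66.2 and 82.65 called, and a mean covariance of 0.0616.

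**Figure D5:**
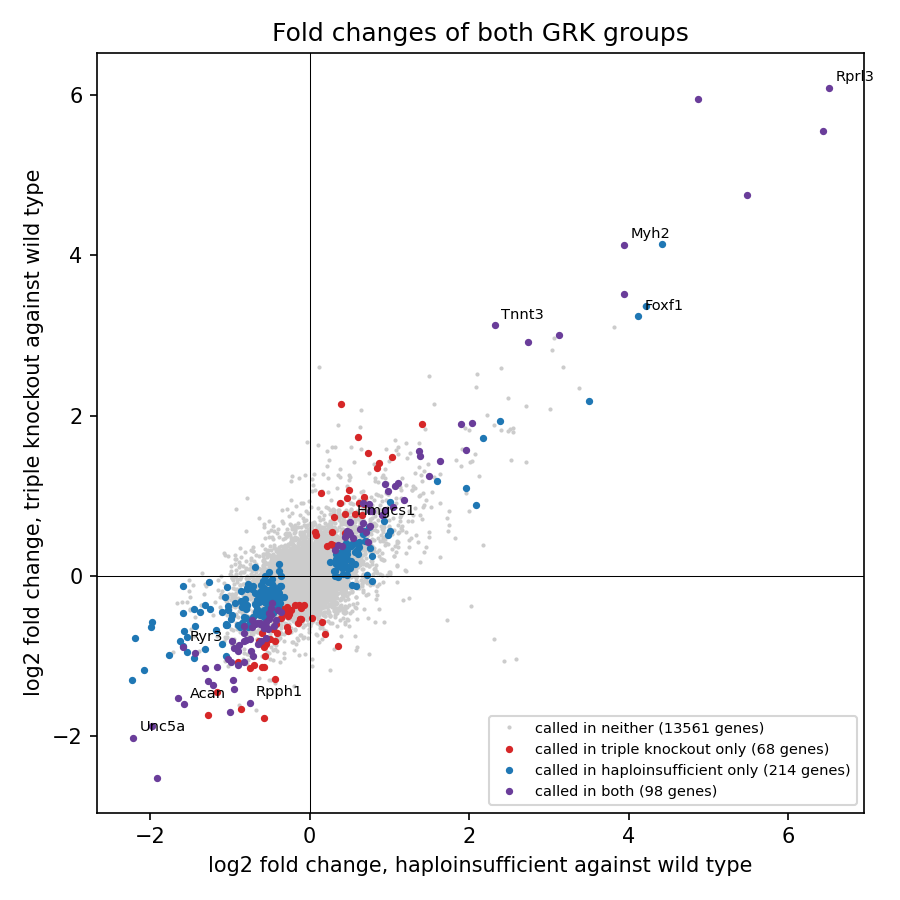
Log2 fold change against wild type of each gene in the triple-knockout group (vertical axis) and in the haploinsufficient group (horizontal axis), coloured by where the gene was called. The 98 genes called in both lie in the quadrants of equal direction.

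DNA near an engineered allele can differ from that of the wild type by strain of origin, so the positions of called genes were compared with the targeted loci. Within 10 Mb of Adrbk1, Grk5, Grk6 or Nkx2-5, these 4 genes themselves left out, 6 of 721 tested genes were called in the triple knockout against 160 of 13220 elsewhere (odds ratio 0.685, 95% interval 0.247 to 1.53, two-sided Fisher's exact p = 0.479). In the haploinsufficient group 17 of 721 were called against 295 of 13220 (odds ratio 1.06, 0.605 to 1.74, Fisher's exact p = 0.796). Windows of 5 and 20 Mb gave odds ratios of 1.08 and 1.30 in the triple knockout and 1.36 and 1.30 in the haploinsufficient group, with Fisher's exact p of at least 0.193. Of the single loci, the 20 Mb around Grk5 held 5 of 141 genes called in the triple knockout (odds ratio 3.11, 0.982 to 7.60, Fisher's exact p = 0.0267, not adjusted for the windows tried), and the 10 Mb around Adrbk1 held 0 of 215 (0 to 1.43, Fisher's exact p = 0.189). By chromosome, calls were more frequent on chromosome 19, which holds Adrbk1 and Grk5, in the triple knockout (14 of 470, odds ratio 2.69, Fisher's exact adjusted p = 0.0311). The haploinsufficient group missed the threshold there (17 of 470, odds ratio 1.68, Fisher's exact adjusted p = 0.284), and the 2 groups were not tested against each other. Chromosome 8, which holds none of the targeted genes, had more calls in both. These were 18 of 748 in the triple knockout (Fisher's exact adjusted p = 0.0478) and 38 of 748 in the haploinsufficient group (Fisher's exact adjusted p = 5.08e-05). Called genes in these windows with the smallest p were Unc5a, on the Grk6 side at chromosome 13 from 54949432 to 55006018, and Glo1, a detoxifying enzyme gene on the Nkx2-5 side at chromosome 17 from 30592862 to 30612659 (0.62 ± 0.10 in the triple knockout and 0.76 ± 0.09 in the haploinsufficient group). Neurl1b near Nkx2-5 was at -0.49 ± 0.12 and -0.48 ± 0.11, Csf2ra near Grk5 at -0.59 ± 0.14 and -0.66 ± 0.14, and Cpt1a, the entry enzyme of fatty acid oxidation near Adrbk1, at -0.49 ± 0.10 in the haploinsufficient group.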

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

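The distance rule was fixed in advance, and the 129 sets of values it was run on were chosen after the data had been read. Each library below lay farther from the others of its group than Dixon's test allows at 95%, which chance alone brings about in roughly 1 in 20 sets, and 11 of 129 sets held such a library. The value given is the gap to the nearest library divided by the range of the group. Grk5 in haploinsufficient replicate 8 stood at 8.24 CPM with the nearest library at 12.6 (0.630). Grk5 exons 7 to 8 in haploinsufficient replicate 2 stood at 2.34 CPM with the nearest at 0.809 (0.654). The cholesterol synthesis score of haploinsufficient replicate 4 was 0.0386 with the nearest at 0.294 (0.667). The cardiac transcription factor score of triple-knockout replicate 7 was -0.476 with the nearest at -0.145 (0.601), and the immediate early gene score of triple-knockout replicate 1 was 0.138 with the nearest at -0.119 (0.582). In the wild-type group, replicate 7 had a conduction and ion channel score of -0.323 with the nearest at -0.0316 (0.623) and a p53 target score of -0.370 with the nearest at -0.0391 (0.645). Wild-type replicate 4 had a Hedgehog target score of 0.645 with the nearest at 0.120 (0.538) and a smooth muscle score of 0.433 with the nearest at 0.0491 (0.595). Wild-type replicate 1 had an amino acid and unfolded protein stress score of -0.156 with the nearest at -0.0170 (0.641), and wild-type replicate 5 a skeletal muscle and cartilage score of 0.609 with the nearest at 0.0934 (0.536).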

How the results depend on the processing

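Tests without libraries of a high lung and foregut score, with that score as a term, with length-corrected offsets and on exon groups were chosen after the results were seen. Unless said otherwise, the cause of a moved value was not tested. With each ID set alone and in the leave-one-out fits there are fewer samples. Tnnt3, Ryr3, Tmem88b and Dynlt1b passed in all 38 settings in which they were compared. Others lost the call in many: Clec4g in 21 of 38 and Aldh1a7 in 20 of 38 in the triple knockout, Cldn6 in 20 of 36, Foxf1 in 17 of 36, Fendrr in 13 of 35, Aldh1a7 in 16 of 37 and Dgkk in 17 of 38 in the haploinsufficient group, and Hist1h2ak in 29, Tmem255a in 27, Frs2 in 26 and Lama2, Anpep, Col6a6 and Slc35b4 in 25 of 38 between the GRK groups. Against wild type, the triple knockout had 166 genes called by edgeR, 279 with DESeq2, 97 with limma on unfiltered log2(FPKM + 1), 296 with only the groups compared, 50 with IDs 1 to 12, 51 with IDs 19 to 30, 83 without the libraries of a high score and 189 with the score as a term. Leaving out single libraries gave 120 to 188. Against wild type, the haploinsufficient group had 312, 528 with DESeq2, 20 with IDs 1 to 12, 179 with IDs 19 to 30, 109 without the libraries of a high score and 155 with the score as a term. It had 165, 196, 194, 203 and 153 without wild-type replicates 1, 2, 6, 7 and 8, and 188, 615, 187 and 183 without haploinsufficient replicates 1, 3, 7 and 8. Between the GRK groups 55 genes were called, 251 with DESeq2, 88 without a filter, 177 with IDs 1 to 12, 1 with IDs 19 to 30, 1 with only the groups compared and 179 with the score as a term. Limma called 0 on log2(FPKM + 1), 0 on log2(FPKM + 0.1) and 0 without a filter (2486, 2519 and 2768 at an unadjusted p under 0.05), and edgeR called 0 without the libraries of a high score and 0 with length-corrected offsets (803 and 1371 at an unadjusted p under 0.05). Without haploinsufficient replicates 1, 2, 3, 4, 7 and 8 the GRK groups differed in 13, 23, 417, 30, 16 and 15 genes, and without triple-knockout replicates 1, 2, 3, 5, 6 and 7 in 16, 11, 10, 97, 27 and 25.

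Against wild type the targeted genes kept their direction. Between the GRK groups, where none passed, Grk5 (0.09) went to -0.14 with IDs 1 to 12 and to -0.00364 without triple-knockout replicate 4, and Grk6 (-0.10) to 0.0206 without haploinsufficient replicate 7. With IDs 1 to 12 the log2 fold changes that no longer passed the edgeR test were -0.48 for Adrbk1 in the triple knockout and -0.85 for Grk5 in the haploinsufficient group. With IDs 19 to 30 they were -0.80 for Adrbk1, -0.58 for Grk5, -0.81 for Grk6 and -0.92 for Nkx2-5 in the triple knockout, and -0.83 for Grk5 and -0.74 for Grk6 in the haploinsufficient group. Adrbk1 in the haploinsufficient group was at -0.68 on its exon group (exact permutation p = 0.0193, not adjusted and so not the same criterion). Nkx2-5 in the haploinsufficient group passed with the replicate number as a block (-0.52) and without haploinsufficient replicates 2 (-0.55), 3 (-0.52) and 5 (-0.56) or triple-knockout replicate 7 (-0.50), and was weakest without haploinsufficient replicate 8 (-0.43). Replicate numbers do not pair the samples: libraries of the same number had mean correlations of -0.0351, -0.0375 and 0.125, 0, 0 and 2 libraries correlated best with their own number, and the block gave 147, 222 and 16 calls for the triple knockout, the haploinsufficient group and the contrast between them. The 98 shared genes became 30.6 on average with the wild-type libraries split, which also cut the calls from 166 and 312 to 66.2 and 82.65.

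Counts of lists include the GPCR kinases and arrestins, which the design changes and which is 1 of the 2 kept against wild type with an estimated correlation in each GRK group. Camera called 8 lists in the triple knockout, 2 with an estimated correlation, 3 with fry, 13 with IDs 1 to 12, 4 without the libraries of a high score and 4 with the score as a term. These are counts of all lists called in a setting. Of the 8 lists, 3 kept the call in each of the last 2 settings, 3 lost it and 2 turned direction. In the haploinsufficient group it called 9, 2 with an estimated correlation and 15 with IDs 19 to 30. Between the GRK groups it called 6, 0 with an estimated correlation, 0 with fry and 15 with IDs 1 to 12. Some lists turned direction without passing the test. In the triple knockout these were the Working myocardium, ventricular list with the score as a term (camera adjusted p = 0.9892), sarcomere genes with the score as a term (0.227) and without the libraries of a high score (0.288), and oxidative phosphorylation without those libraries (0.373). Between the GRK groups they were oxidative phosphorylation (0.925) and neural crest markers (0.538) with IDs 19 to 30. Depth limits the exon groups, with 62 to 150 counts per group on Adrbk1 exons 3 to 6 and 23 to 156 on Grk5 exons 7 to 8.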

Other observations

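Some tests in this part were chosen after the results were seen. They are those on the Hedgehog targets and the lung score and on the genes shared by both GRK groups. The same holds for reading the draws matched to the histone genes by themselves. The genes of this paragraph were chosen after their values were seen. Single genes fell in both GRK groups. The slow skeletal troponin gene Tnnt1 went from 293.6 ± 37.8 CPM in wild-type hearts to 150.8 ± 33.2 in haploinsufficient and 119.9 ± 34.6 in triple-knockout hearts (-0.96 and -1.30, edgeR adjusted p = 0.000366 and 6.26e-06). The stress-responsive genes Ankrd1 (-0.62 and -0.58) and Nppb (-0.75 and -0.79), the cardiac gene Lrrc10 (-0.89 and -0.86) and Ndrg4 (-0.99 and -1.07) fell too. They were not tested as a group. The fatty acid desaturase gene Scd1, which like cholesterol synthesis is driven by sterol regulatory element binding proteins, rose by 1.39 and 1.49. The tubulin gene Tuba1c rose by 1.63 and 1.44, and Wdfy1 went from 19.4 ± 2.44 to 41.8 ± 2.65 and 43.5 ± 2.98 CPM (1.11 and 1.16, edgeR adjusted p = 2.62e-09 and 9.06e-10).

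Among blood and growth genes in the triple knockout, the macrophage receptor gene Mrc1 rose (0.77 ± 0.17) while Lyz2 (-1.14 ± 0.24) and the platelet integrin gene Itga2b (-0.84 ± 0.21) fell. The myeloid and blood list was not called (camera adjusted p = 0.125), and adjusted over the list alone 3 members rose and 3 fell. The imprinted gene Peg3 rose (0.51 ± 0.11) and the imprinted cell cycle inhibitor gene Cdkn1c fell (-0.54 ± 0.13), with 2 and 1 adjusted over the list alone (camera adjusted p = 0.207).

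Hedgehog targets varied with the markers of neighbouring tissue. Their score averages the listed members, whether signalling raises or lowers them. Within groups, the Hedgehog target score and the lung, foregut, liver and thymus score had a correlation of 0.868 over 23 libraries (permutation p = 1e-05, the smallest possible; rho 0.876; the only relation computed). It was 0.701 in wild-type, 0.955 in haploinsufficient and 0.929 in triple-knockout libraries, 0.831 and 0.867 in the ID sets, and 0.914 without the libraries farthest out, haploinsufficient replicate 6 and wild-type replicate 7. Without the lung score, the difference from wild-type hearts was 0.338 in the triple knockout and 0.258 in the haploinsufficient group. With the score as a term it was -0.201 (95% interval -0.558 to 0.156) and -0.310 (-0.661 to 0.0413), so its sign turned in both. A separate exact permutation of residuals on the lung score, without the ID set term, gave p = 0.561 and 0.234. A higher Hedgehog target score beyond that of the lung markers was therefore not borne out in either group. The intervals leave an effect open in both. The lung list was also set up with Shh, a listed Hedgehog pathway component, so the term may take out Hedgehog activity itself. Cdon, 1 of the targets, kept its call between the GRK groups in 30 of 38 settings. Those were all the leave-one-out fits, which reuse most of the data, and some others, among them that with the score as a term. Cdon lost the call in 8, none of them leave-one-out. Among these were the fits without the libraries of a high score, with length-corrected offsets, with IDs 19 to 30 alone and with limma on unfiltered FPKM. Unequal amounts of lung and foregut tissue dissected with the heart may explain the variation in Foxf1, Gli1 and Fendrr. A shift of cell types inside the heart was not tested.

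The lower Hist genes of the triple knockout against the haploinsufficient group coincide with a trend over gene length. With length-corrected offsets the median log2 fold change of the 55 Hist genes went from -0.67 to -0.33, a share of 0.497, and the called ones from 17 to 0. By the bounds set in advance, a share under 0.25 would have spoken for length. A share over 0.5 would have spoken against it, if draws of matched genes also gave p under 0.05. The share falls just short of the upper bound, which was not moved, so this test leaves the matter open. Of 2000 draws of genes matched in length and expression the lowest median was -0.379 (one-sided permutation p over these draws = 5e-04, the smallest possible). The Hist genes thus lay below all draws. The matched genes were longer, at a median of 584 nt against 468 nt, and were drawn singly, whereas Hist copies share sequence. The draws therefore speak against length alone as the whole cause but do not exclude it. S phase genes kept a median of -0.146 after the correction (camera adjusted p = 0.000413, and adjusted p = 0.760 with an estimated correlation). Fewer cycling cells than in the haploinsufficient group therefore remain possible. Against wild type the list was not lower in the triple knockout, with a median of 0.07 and 18 of 24 members positive (camera adjusted p = 0.125). In the haploinsufficient group 23 members were positive against wild type, with a median of 0.23.

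The genes called in both GRK groups could reflect loss of the kinases, the Cre allele or strain background, which all coincide here. No group separates the loss of the GRK alleles from the others, so how many of the 98 genes it explains cannot be told. The lung, foregut, liver and thymus score was also higher on average in the haploinsufficient (1.07) and triple-knockout (0.955) groups than in wild type (0). Neighbouring tissue may thus contribute as well. How many of the 98 genes stay called without the libraries of a high score was not counted. Of the 98 genes, 4 lie within 10 Mb of the targeted loci (odds ratio 0.777, 0.207 to 2.07, Fisher's exact p = 0.819), an interval too wide to exclude DNA flanking the loci. The other 94 genes held 13 neighbouring pairs against a mean of 3.30 and a highest of 12 in 10000 permutations (p = 1e-04, the smallest possible), and 11 pairs without a shared symbol start (permutation p = 6e-04), as blocks of another strain's DNA could give. Several pairs share genes and so stand for fewer places in the genome. These were pairs among Nnt, Gm7120 and Hmgcs1 on chromosome 13, and among Synj2, Tmem181a, Dynlt1b and Tmem181b-ps on chromosome 17. Tnni2 and Tnnt3 on chromosome 7, a pair among the 13 but not among the 11, may also be co-regulated neighbours. Whether any of the 11 are co-regulated neighbours was not tested, so the test does not settle which cause holds.

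Chance regrouping of the libraries was tried with 100 groupings for each comparison, the real one included, and not with all that are possible. For the triple knockout only the real grouping reached the count (166, highest other 36), which speaks against chance as its source. In the haploinsufficient group only the real grouping reached 312, but the highest other gave 283. Leaving out single libraries moved that count from 153 to 615, so this speaks against chance less firmly and does not exclude it. Between the GRK groups 8 groupings, the real one included, reached the count (55, highest other 1243). Chance was not excluded there, and the regroupings point to other structure among the samples. Xist was higher than Y-linked genes in 5 wild-type, 5 haploinsufficient and 3 triple-knockout libraries and lower in 3, 3 and 4. Several libraries held both: wild-type replicate 7 had 71.7 CPM of Xist and 62.1 of Y-linked genes and haploinsufficient replicate 7 had 120.7 and 43.3, so this tally, and the sex term made from it, assigns some libraries uncertainly.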
